A study of Homo sapiens with 8 samples.

How the data were processed

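Total RNA of 8 samples of human cell lines was hybridised to Affymetrix arrays, 1 array per sample. HepG2 is a hepatocellular carcinoma line and LX2 a line of hepatic stellate cells. Cells were seeded at 200000 per well of 6-well plates and received CM272, a dual inhibitor of the histone methyltransferase G9a and the DNA methyltransferase DNMT1, at 400 nM for 48 h, or 0.1% DMSO. HepG2 was kept with 10% fetal bovine serum and LX2 with 2%, so that line and serum level always went together. RNA was isolated on an automated Maxwell instrument, and 300 ng per sample was amplified with an Ambion whole-transcript kit and labelled with the Affymetrix kit.

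The deposited table holds log2 expression values, which the authors background-corrected, normalized between arrays and summarised per probe set with RMA, per the submitters' processing notes (software version not given in the sources used here). The values ran from 0.49 to 14.07 over the 8 arrays, and they were used on the log2 scale as deposited. RMA sets a common distribution of intensities across arrays, so a change shared by most genes of a group would be removed in part. It also compresses folds of dim genes towards 0. Array medians lay between 4.19 and 4.54. Arrays give no counts, so that the precision of each value is limited by the number of arrays.

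Of 48416 probe sets, 16098 (33.2%) had 1 gene symbol in the platform annotation used here, and 32318 had no symbol there. All 16098 matched a current gene record by gene identifier, and 0 symbols needed an update. The genome build of the array design was not given in the sources used here, so no coordinates are reported. For each of 14884 symbols the probe set with the highest mean over the 8 arrays was kept (779 symbols had more than 1). A probe set can share its values with another, as 403 named probe sets did. Genes entered the tests when their log2 value was over 4 in both arrays of at least 1 group, which left 12239 genes and set aside 2645 as too dim.

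The groups were LX2 control, LX2 CM272, HepG2 control and HepG2 CM272, with 2 arrays in each. The comparisons were CM272 against control in each line, the difference of the CM272 effect between the lines (the change in HepG2 minus the change in LX2), and HepG2 control against LX2 control. All came from 1 fit of limma 3.58.1 in R 4.3.3 with a mean per group and the default moderated variance (4 residual and 5.47 prior degrees of freedom). Benjamini-Hochberg adjustment was made over the 12239 genes, with a threshold of 0.05 on the adjusted p. All limma tests were two-sided. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so single genes were tested only with limma. The overlap of calls between lines was tested with a two-sided Fisher's exact test. Figures were drawn with matplotlib 3.10.9.

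Before the data were examined, 33 gene lists of 15 to 37 members were fixed. They covered the G9a and DNA methylation machinery, interferon-stimulated genes, MHC class I antigen presentation, germline and cancer-testis genes, imprinted genes, neuronal genes, G1/S and DNA replication, mitosis, p53 targets, cholesterol biosynthesis, fatty acid synthesis, glycolysis, hypoxia response, gluconeogenesis and hepatic fuel metabolism, and hepatocyte plasma proteins. Further lists held hepatocyte transcription factors, bile acid and drug metabolism, fetal liver and progenitor genes, extracellular matrix, myofibroblast contractile genes, TGF-beta targets, stellate cell markers, inflammatory cytokines and NF-kB targets, and unfolded protein response and ATF4 targets. The rest were serine, glycine and one-carbon metabolism, lysosome and autophagy, oxidative phosphorylation, NRF2 targets and metallothioneins, apoptosis regulators, silenced tumour suppressors, leukocyte markers, endothelial markers and housekeeping genes. Members with no symbol or too dim to test dropped out, so each list stands for part of its program. Tested were, for instance, 5 of 19 MHC class I, 8 of 22 glycolysis and 9 of 28 oxidative phosphorylation genes. The 32 lists with at least 5 tested members were tested against all other genes with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stand camera with a correlation estimated from the data and fry, which asks whether a list's genes move one way on balance.

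Named genes were chosen by a rule set at the same time. It took the 10 largest rises and 10 largest falls past the adjusted threshold in each treatment comparison whose treated arrays both lay beyond both control arrays, and the 5 largest each way in the other comparisons. It added 2 to 4 members past the threshold per list, or up to 2 as values where none passed, and always EHMT2, EHMT1, DNMT1 and UHRF1. Unnamed loci, non-coding and immune receptor segments, read-through names and sex-chromosome genes that reveal sex were skipped. Any gene outside the rule is named as chosen after its values were seen.

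The procedure was tested on simulated data with 1 spread per gene, pooled over the groups of these arrays (10 simulations, 200 changed genes in each line). In LX2 it recovered 13.1% of changes of log2 0.5, 92.5% of those of log2 1 and 100% of those of log2 2, and in HepG2 12.7%, 91.9% and 100%. False calls made up 5.39% and 7.42% of all calls. Camera called 10 of 10 lists of 20 genes shifted by 0.4 and 1 of 10 unshifted lists, and with an estimated correlation 10 of 10 and 0 of 10 at an unadjusted p under 0.05 (camera from limma). These rates hold for equal spread in all groups and independent genes. The real LX2 CM272 replicates lay further apart than the LX2 controls (median difference 0.26 against 0.12 log2). Genes of a list can also be correlated (0.31 estimated for cholesterol biosynthesis), which the simulation did not cover.

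Alternatives fixed before the data were examined were no filter, a filter at log2 6, all probe sets, median centring, quantile normalization over all arrays or within each line, a trend and robust variance prior, array weights, each line fitted alone, a block by replicate number, a 2-fold minimum, an adjusted p under 0.01, limma's B statistic over 0, and leaving out each array in turn. A fit without the LX2 CM272 group and the members called per list without each LX2 CM272 array were added after seeing the data.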

Results

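Gene expression was measured on Affymetrix whole-transcript arrays in HepG2, a human hepatocellular carcinoma line, and LX2, a line of human hepatic stellate cells, the cells that turn into collagen-producing myofibroblasts in injured liver. Each line received CM272 at 400 nM for 48 h or 0.1% DMSO as control. CM272 inhibits both the histone methyltransferase G9a (encoded by EHMT2) and the maintenance DNA methyltransferase DNMT1, a pair of enzymes that keep genes silent. The 8 arrays formed 4 groups with 2 arrays in each, and the n of every value below is 2 arrays per group. HepG2 was grown in 10% serum and LX2 in 2%, so a difference between the lines cannot be separated from serum. Values are log2 expression values for 14884 gene symbols, of which 12239 were bright enough to test.

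The replicate arrays correlated across genes at r = 0.992 (LX2 control), 0.970 (LX2 CM272), 0.990 (HepG2 control) and 0.987 (HepG2 CM272), where genes are not independent replicates. The median absolute difference between replicates was 0.12, 0.26, 0.14 and 0.15 log2, in the same order. The LX2 CM272 arrays stood furthest apart, with 183 genes differing by more than log2 1 against 12 in the LX2 control, and LX2 CM272 replicate 1 had the highest array median (4.54). Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples.

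What simultaneous inhibition of G9a and DNMT1 does to the transcriptome of hepatic stellate cells was addressed by comparing LX2 with and without CM272. A small set of genes rose steeply in LX2 with CM272. TEX14 (probe set 16847164), a protein of the intercellular bridges between germ cells, rose by log2 5.37 (SE 0.23), from 3.90 ± 0.06, under the brightness filter of log2 4, to 9.27 ± 0.28 (SD), so that its fold is not exact. USP17L12 and USP17L9P, deubiquitinase genes of a multi-copy family, shared all their array values and rose by 4.69 (SE 0.17). FOSB (probe set 16863287), a subunit of the AP-1 transcription factor, rose by 4.16 (SE 0.15), and SNAI1 (probe set 16914791), a repressor that drives epithelial-mesenchymal transition, by 3.86 (SE 0.15). Across the genome 1031 of 12239 genes changed (464 higher and 567 lower, limma with Benjamini-Hochberg adjustment), and 138 of the higher and 79 of the lower genes changed at least 2-fold.

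The other large rises in LX2 were USP17L15 (4.12, SE 0.21, not exact because its control mean of 3.18 lay under the filter), RELN, an extracellular glycoprotein best known from neuronal migration (3.93, SE 0.14), the zinc finger gene ZNF280A (3.84, SE 0.16), PCDH10, a protocadherin (2.81, SE 0.18), and GTF2B, general transcription factor IIB (2.64, SE 0.21). Adjusted p-values from limma for these 10 genes ran from 7.39e-07 for FOSB to 3.02e-04 for GTF2B. The largest falls were smaller. PPA2, the mitochondrial pyrophosphatase, fell by 1.57 (SE 0.26), the pseudogene HNRNPA1P33 by 1.54 (SE 0.32, to a mean of 3.97 under the filter) and MEST, an imprinted gene, by 1.52 (SE 0.13, limma adjusted p = 5.42e-04). LRRC37B fell by 1.49, CXADRP3 by 1.43, ZBTB41 by 1.37, IPP, a kelch protein, by 1.36, CMKLR2, a chemerin receptor, by 1.36, LXN, a carboxypeptidase inhibitor, by 1.30 and DTWD1 by 1.28. Several of these falls came with widely separated CM272 arrays, as for PPA2 (3.62 and 4.61, against 5.64 and 5.73 in control) and LRRC37B (3.94 and 5.33).

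**Figure D1:**
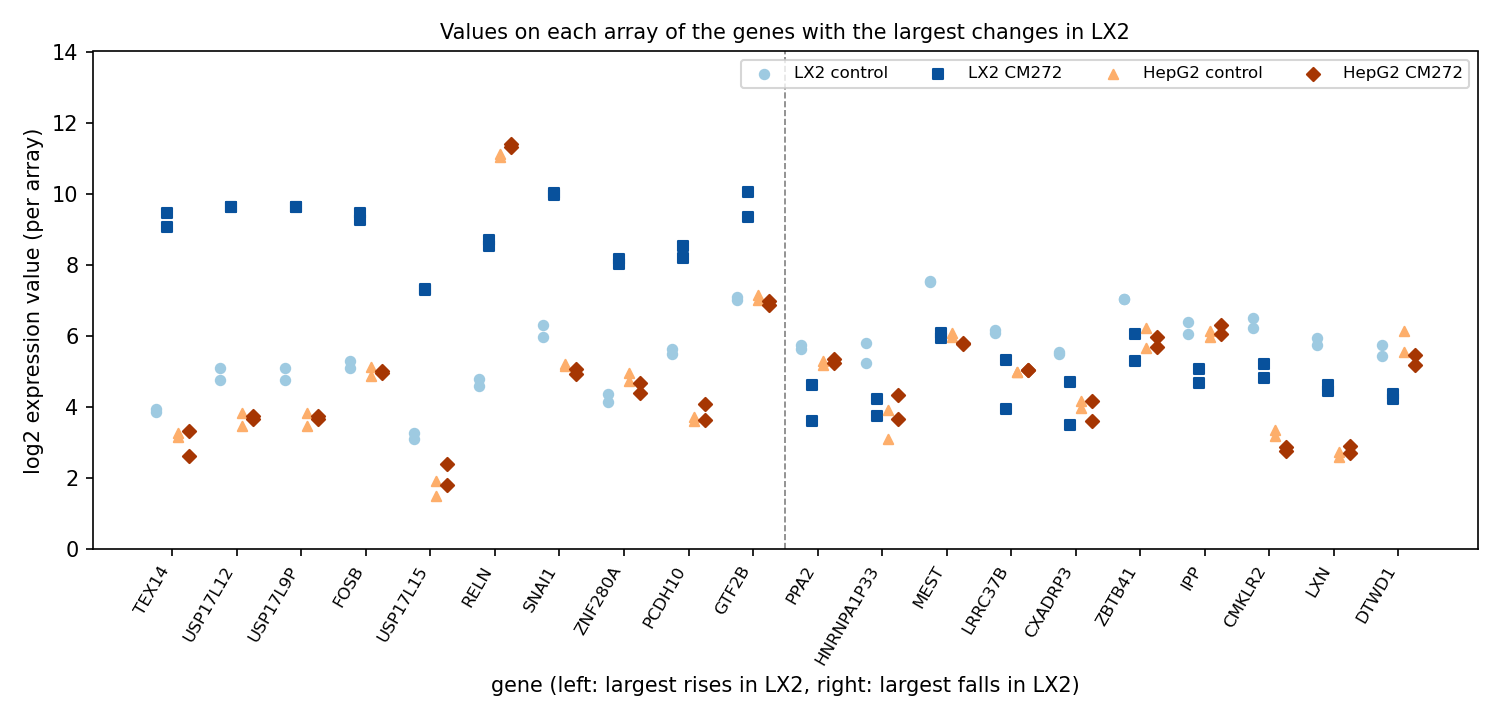
Log2 expression values on each of the 8 arrays for the 10 genes with the largest rises (left of the dashed line) and the 10 with the largest falls (right) in LX2 with CM272; each point is 1 array, coloured by group. For the rises both LX2 CM272 arrays lie far above all LX2 control arrays, as for TEX14 (means of 3.90 and 9.27).

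Transcripts of the drug's own targets did not pass the test in LX2. EHMT2 differed by 0.02 (SE 0.16, adjusted p = 0.954 in limma), EHMT1, its partner GLP, by -0.06, DNMT1 by 0.24 (adjusted p = 0.323) and UHRF1, which recruits DNMT1 to replicated DNA, by 0.37 (adjusted p = 0.155). Of 16 genes of the G9a and DNA methylation machinery 1 fell, the heterochromatin protein gene CBX3 (-1.02, SE 0.20), also the only call adjusted over the list alone. TEX14 was the 1 of 7 germline and cancer-testis genes that rose, with or without adjustment over the list alone (list median 0.10, camera adjusted p = 0.299), and the median was -0.14 without LX2 CM272 replicate 1. Among 13 imprinted genes PEG10 (1.26, SE 0.15) and MEG3 (0.58, SE 0.13) rose and MEST fell, against 3 higher and 2 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.688; -0.25 without LX2 CM272 replicate 1). The neuronal genes, a class kept silent outside the nervous system, had a median of 0.21 and passed camera (adjusted p = 0.0411), but the call was lost with an adjusted p = 0.635 with an estimated correlation. In that list SCG2, which encodes secretogranin II, rose (0.86, SE 0.16), the other 13 of 14 did not pass, and 4 were higher adjusted over the list alone. Without LX2 CM272 replicate 1 the median of the neuronal genes was 0.14 (camera adjusted p = 0.383), and the call was lost with fry and in 9 further settings, among them no filter (0.279, median 0.07) and quantile normalization over 8 arrays (0.131). Of 21 tumour suppressors often silenced by methylation 1 rose, IGFBP3 (0.68, SE 0.16), with 2 higher and 2 lower adjusted over the list alone (median -0.04).

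Some inflammatory and interferon-stimulated genes rose in LX2. Of 19 inflammatory cytokines and NF-kB targets 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a list median of 0.41. PTGS2, the inducible cyclooxygenase, rose by 2.21 (SE 0.22), the chemokine CCL20 by 2.03 (SE 0.26, from a control mean of 3.58 under the filter), the adhesion molecule ICAM1 by 1.26 (SE 0.16) and the chemokine CCL5 by 1.15 (SE 0.16). The list passed limma's camera at an adjusted p = 6.37e-04, which was lost with an adjusted p = 0.52 with an estimated correlation. Of 26 interferon-stimulated genes 3 rose, namely OASL, a 2'-5'-oligoadenylate synthetase-like antiviral protein (2.38, SE 0.19), IFI44L (1.11, SE 0.14, from a control mean of 3.32 under the filter) and IRF7, a master regulator of interferon induction (0.98, SE 0.25). Adjusted over the list alone 4 were higher and 1 lower, the list median was 0.35, and camera gave an adjusted p = 6.37e-04, lost with an adjusted p = 0.52 with an estimated correlation. The inflammatory call held without either LX2 CM272 array (adjusted p = 2.09e-04 and 0.0196), whereas the interferon call was lost without LX2 CM272 replicate 2 (median 0.27, adjusted p = 0.0591). Without LX2 control replicate 1 or 2 both camera calls held, but only 4 and 2 inflammatory and 2 and 1 interferon-stimulated genes rose, and none of either list fell. None of 5 MHC class I genes passed limma (0 called, 1 at an unadjusted p under 0.05, 0 adjusted over the list alone), with ERAP2 at 0.32 and TAPBP at 0.16. Of the markers of other cell types, CD14 rose among 10 leukocyte markers (1.12, SE 0.18) and FLT1, a VEGF receptor, among 9 endothelial markers (1.55, SE 0.20). Each was also the only call adjusted over the list alone, and neither list passed camera (adjusted p = 0.299 and 0.202; medians of 0.02 and -0.04 without LX2 CM272 replicate 1).

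Part of the genes of cholesterol biosynthesis fell in LX2 with CM272. Of 18 tested members 5 fell (8 adjusted over the list alone) and the median was -0.43. SQLE (probe set 17072552), squalene epoxidase, fell by 1.16 (SE 0.15), INSIG1, the sterol-regulated anchor of SREBP processing, by 0.81 (SE 0.13), HMGCS1, which makes HMG-CoA, by 0.69 (SE 0.16) and STARD4, a cholesterol carrier, by 0.68 (SE 0.17). Camera gave an adjusted p = 0.0080, lost with an adjusted p = 0.635 with an estimated correlation. The list median was -0.48 without LX2 CM272 replicate 1 (adjusted p = 0.0189) and -0.36 without replicate 2 (adjusted p = 0.0591). The number of members that fell was 1 without LX2 control replicate 1 or with each line fitted alone, and 0 in limma without LX2 control replicate 2 (10 at an unadjusted p under 0.05 with all arrays). Fatty acid synthesis genes had a median of -0.22, with 4 of 18 lower and 1 higher (5 and 1 adjusted over the list alone). ACSL4 (-0.99, SE 0.19), the stearoyl-CoA desaturase SCD (-0.88, SE 0.15) and the acetyl-CoA synthetase ACSS2 (-0.68, SE 0.17) fell, and DGAT1, which makes triglyceride, rose (0.71, SE 0.18). That list's camera call (adjusted p = 0.0411) was lost with an adjusted p = 0.635 with an estimated correlation, and its median was -0.44 without LX2 CM272 replicate 1 and -0.12 without replicate 2 (adjusted p = 0.364). It was also lost without LX2 control replicate 1 (0.0812), with quantile normalization over 8 arrays (0.123) and within each line (0.118), and with the filter at log2 6 (0.220). No fatty acid synthesis gene was called in limma without either LX2 control array or with each line fitted alone (0 in each, against 1 higher and 7 lower at an unadjusted p under 0.05 with all arrays).

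Other metabolic groups moved by few members. In glycolysis 1 of 8 fell, LDHA (-0.97, SE 0.13), as adjusted over the list alone (median -0.15). Of 21 hypoxia response genes 4 rose and 3 fell (4 and 4 adjusted over the list alone), among them ADM (0.93, SE 0.16) and NDRG1 (0.81, SE 0.18) upward and ERO1A (-1.02, SE 0.20) and the collagen cross-linker LOX (-1.01, SE 0.15) downward. Pyruvate carboxylase, PC, rose (0.75, SE 0.15) as 1 of 11 genes of gluconeogenesis and hepatic fuel metabolism, with 3 higher adjusted over the list alone and a median of 0.22 (camera adjusted p = 0.0752). That median was 0.01 without LX2 CM272 replicate 1 and 0.41, past camera at an adjusted p = 0.0196, without replicate 2. Serine, glycine and one-carbon genes had a median of -0.32, yet the 2 of 14 that passed rose, CTH (1.19, SE 0.28) and GLDC (1.05, SE 0.19), and adjusted over the list alone 2 were higher and 5 lower. Hepatocyte plasma proteins, dim in this line, had a median of 0.21 and a camera adjusted p = 0.0181, lost with an adjusted p = 0.635 with an estimated correlation. HP, haptoglobin, was the 1 of 26 that rose (0.76, SE 0.19), 0 passed in limma when adjusted over the list alone, and 5 were higher and 1 lower at an unadjusted p under 0.05. Without LX2 CM272 replicate 1 that median was -0.01 (adjusted p = 0.383), and the call was lost with quantile normalization over 8 arrays (0.146) and within each line (0.144). ATF5 (0.66, SE 0.16) and PROX1 (0.60, SE 0.16) rose among 7 hepatocyte transcription factors (3 adjusted over the list alone, median 0.12). Their median was -0.0048 without LX2 CM272 replicate 1 and 0.25 without replicate 2, and 0 were called in limma without either LX2 control array (3 at an unadjusted p under 0.05 with all arrays). In the bile acid and drug metabolism list, with 4 measured members too few for a list test, BAAT, which conjugates bile acids, rose (0.92, SE 0.16). KRT19 rose (0.67, SE 0.15) and CD44 fell (-0.61, SE 0.15) among 20 fetal liver and progenitor genes (2 higher and 1 lower adjusted over the list alone, median 0.10).

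Mitosis genes shifted slightly downward, with few and unstable calls. CCNA2, the cyclin of S and G2 phase, fell by 0.71 (SE 0.13), and the mitotic motors KIF23 and KIF11 by 0.71 each (SE 0.16 and 0.15). These were the 3 of 28 past the test (4 lower adjusted over the list alone), with a list median of -0.26 and a camera adjusted p = 0.0181, lost with an adjusted p = 0.635 with an estimated correlation. Without LX2 CM272 replicate 1 the mitosis median was -0.18 and 1 member rose and 1 fell (camera adjusted p = 0.223), while without replicate 2 it was -0.31 with 2 higher and 9 lower (0.0157). No mitosis gene was called in limma without LX2 control replicate 1 or 2, with array weights or with each line fitted alone (0 in each, against 1 higher and 10 lower at an unadjusted p under 0.05 with all arrays). The list's camera call was lost with quantile normalization over 8 arrays (0.141) and the filter at log2 6 (0.148). G1/S and DNA replication genes went both ways, with GINS1 lower (-0.80, SE 0.15) and CDC45 higher (0.50, SE 0.13) of 24, and 1 higher and 2 lower adjusted over the list alone (median 0.02). Of 15 p53 targets PMAIP1, which encodes the death protein NOXA (0.85, SE 0.20), and SESN2 (0.82, SE 0.17) rose while CCNG1 (-0.92, SE 0.19) and POLK (-0.68, SE 0.17) fell, against 2 higher and 4 lower adjusted over the list alone (median 0.00). Of 16 apoptosis regulators PMAIP1 rose and BIRC2, an inhibitor of apoptosis, fell (-0.96, SE 0.16), with 1 higher and 2 lower adjusted over the list alone (median 0.05).

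In the stress lists single genes rose steeply. MT1G, a metallothionein, rose by 2.24 (SE 0.34, from a control mean of 2.53 under the filter) and TXNRD1, thioredoxin reductase, fell by 0.66 (SE 0.17) among 11 NRF2 targets and metallothioneins (2 higher and 1 lower adjusted over the list alone, median 0.02). ATF3 (1.76, SE 0.21), DDIT3, also known as CHOP (0.92, SE 0.20), and SESN2 rose among 14 unfolded protein response and ATF4 targets, with 3 higher and 2 lower adjusted over the list alone. The median of that list was -0.24 and its mean 0.05, of opposite sign. NEU1 (0.83, SE 0.16) and MCOLN1 (0.59, SE 0.14) rose and the protease CTSL fell (-0.61, SE 0.16) among 19 lysosome and autophagy genes, as they did adjusted over the list alone. The median of that list was 0.05 with all arrays and -0.06 without LX2 CM272 replicate 1. No oxidative phosphorylation gene passed limma (0 of 9, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone, median 0.09), with COX5A at -0.48 and COX5B at 0.21. No housekeeping gene passed either (0 of 7, 1 at an unadjusted p under 0.05, 0 adjusted over the list alone in limma, median -0.11), with HPRT1 at -0.63 and PGK1 at -0.16.

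The tested genes of stellate cell identity and fibrosis showed no common direction in LX2. They were only part of the fixed lists, with 15 of 37 extracellular matrix genes, 14 of 22 contractile genes, 11 of 26 TGF-beta targets and 17 of 27 stellate cell markers. Of 15 extracellular matrix genes LOX and THBS2, a matricellular protein (-0.69, SE 0.18), fell, with 2 higher and 4 lower adjusted over the list alone (median -0.22, camera adjusted p = 0.616), and the median was 0.12 without LX2 CM272 replicate 2. The myofibroblast contractile genes had DES, desmin, higher (1.25, SE 0.28) and TPM1, a tropomyosin, lower (-0.81, SE 0.15) of 14, with 2 higher and 1 lower adjusted over the list alone (median -0.07). Of 11 TGF-beta targets SNAI1, JUNB (0.98, SE 0.24) and CCN2, connective tissue growth factor (0.64, SE 0.15), rose, against 5 higher and 3 lower adjusted over the list alone (median 0.07, camera adjusted p = 0.311). The TGF-beta median was -0.09 without LX2 CM272 replicate 1, with 2 members higher and 4 lower. None of 17 stellate cell markers passed limma (0 called, 4 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, median -0.05), with NGFR at 0.49 and TCF21 at 0.47. The sign of the mean differed from that of the median in 8 of the 32 lists, none of them called by camera: G1/S, p53 targets, contractile genes, stellate markers, unfolded protein response, oxidative phosphorylation, apoptosis and silenced tumour suppressors.

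In all, 3098 genes had an unadjusted p under 0.05 in LX2, against 612 from chance alone if all groups had the same spread. The LX2 CM272 arrays lay further apart than the LX2 controls (median difference 0.26 against 0.12 log2), while limma used 1 variance for all groups. Chance alone therefore likely gives more than 612 in LX2, and the excess is overstated. Camera called 7 of 32 lists, none of which passed with an estimated correlation (0 calls, smallest adjusted p = 0.520) or with fry (0 calls, smallest adjusted p = 0.0599). The estimated correlation decides little here, as it passed no list between the control groups either, where fry called 28. The count of 1031 was 98 and 56 without LX2 control replicate 1 or 2, 573 without either HepG2 control array, 2493 without LX2 CM272 replicate 2 and 810 without replicate 1. The share of calls that were higher depended on scaling and on the control arrays, at 45.0% with all arrays as deposited, 83.7% and 91.1% without LX2 control replicate 1 or 2, 66.7% with each line fitted alone and 30.6% after median centring (338 higher and 766 lower), the last of which moved the median of all genes from -0.02 to -0.09. Over 4 groups of genes of like size, from the dimmest to the brightest, the median change in LX2 was 0.08, 0.03, -0.08 and -0.14, with 134 higher and 36 lower in the dimmest and 78 and 247 in the brightest.

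The same exposure in the carcinoma line HepG2 left few single-gene calls. C5AR1 (probe set 16863589), the receptor for complement fragment C5a, fell by 1.89 (SE 0.17, a 3.71-fold change, limma adjusted p = 0.0122), from 6.36 ± 0.05 to 4.46 ± 0.01 (SD). It was the only gene of 12239 past the test, while 1403 had an unadjusted p under 0.05 against 612 from chance alone if all groups had the same spread. The target transcripts did not pass, with EHMT2 at 0.37 (SE 0.16, adjusted p = 0.418), EHMT1 at 0.15, DNMT1 at -0.05 and UHRF1 at 0.12. The C5AR1 call was lost, giving 0 calls in limma, when any 1 of the HepG2 arrays or of the LX2 control arrays was left out, when HepG2 was fitted alone and when all probe sets were tested. Its adjusted p ran from 6.37e-04 to 0.240 over the alternatives, and none of the alternatives turned its direction.

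Camera called 5 lists in HepG2, with small median changes. Of the cholesterol biosynthesis genes 17 of 18 lay above 0, with a median of 0.42, and among them were MVD at 0.61 (SE 0.23) and ACAT2 at 0.61 (SE 0.23). None passed limma alone (0 called, 9 higher at an unadjusted p under 0.05, 3 adjusted over the list alone), and camera gave an adjusted p = 3.85e-09, lost with an adjusted p = 0.685 with an estimated correlation. Hepatocyte plasma proteins had 24 of 26 members above 0 and a median of 0.24, with HP at 1.42 (SE 0.19, adjusted p = 0.117) and HPX, hemopexin, at 0.75 (SE 0.18). For them 0 were called, 6 were higher at an unadjusted p under 0.05 and 3 adjusted over the list alone in limma, and the camera adjusted p = 5.92e-07 was lost with an adjusted p = 0.685 with an estimated correlation. Both of these list calls held when any 1 of the 8 arrays was left out, while the cholesterol median ran from 0.26 without HepG2 CM272 replicate 2 to 0.61 without replicate 1.

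A further 3 lists passed camera in HepG2, each without a single member past limma. Interferon-stimulated genes had a median of 0.22, with USP18 at 0.75 and the RNA sensor IFIH1 at 0.55 (0 called, 6 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone). Their camera adjusted p = 0.0139 was lost with an adjusted p = 0.685 with an estimated correlation, and with 0.103 without HepG2 control replicate 1 and 0.120 without HepG2 CM272 replicate 2. G1/S genes had a median of 0.12, with DTL at 0.44 and E2F8 at 0.36 (0 called, 2 higher at an unadjusted p under 0.05, 0 adjusted over the list alone). Camera's adjusted p = 0.0350 there was lost with an adjusted p = 0.697 with an estimated correlation, and with 0.238 and 0.540 without those same arrays (medians of 0.10 and 0.05). It was lost as well with no filter (0.0609), all probe sets (0.107) and each line fitted alone (0.0538). Inflammatory cytokines and NF-kB targets had a median of -0.20, with the cytokine LIF at -1.30 (SE 0.27) and the chemokine CXCL8 at -0.81 (SE 0.19), 0 called, 5 lower at an unadjusted p under 0.05 and 3 lower adjusted over the list alone. Their adjusted p = 0.0335 was lost with an adjusted p = 0.697 with an estimated correlation, with 0.117 and 0.513 without the same HepG2 arrays, with 0.0772 without either LX2 CM272 array, with 0.0525 at the filter of log2 6 and with 0.0660 when each line was fitted alone. Fry called none of the 32 lists (0 calls, smallest adjusted p = 0.284), and the remaining lists did not pass camera (smallest adjusted p = 0.115, fatty acid synthesis). The mean and median differed in sign for the imprinted, hypoxia, fetal liver and oxidative phosphorylation lists.

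**Figure D2:**
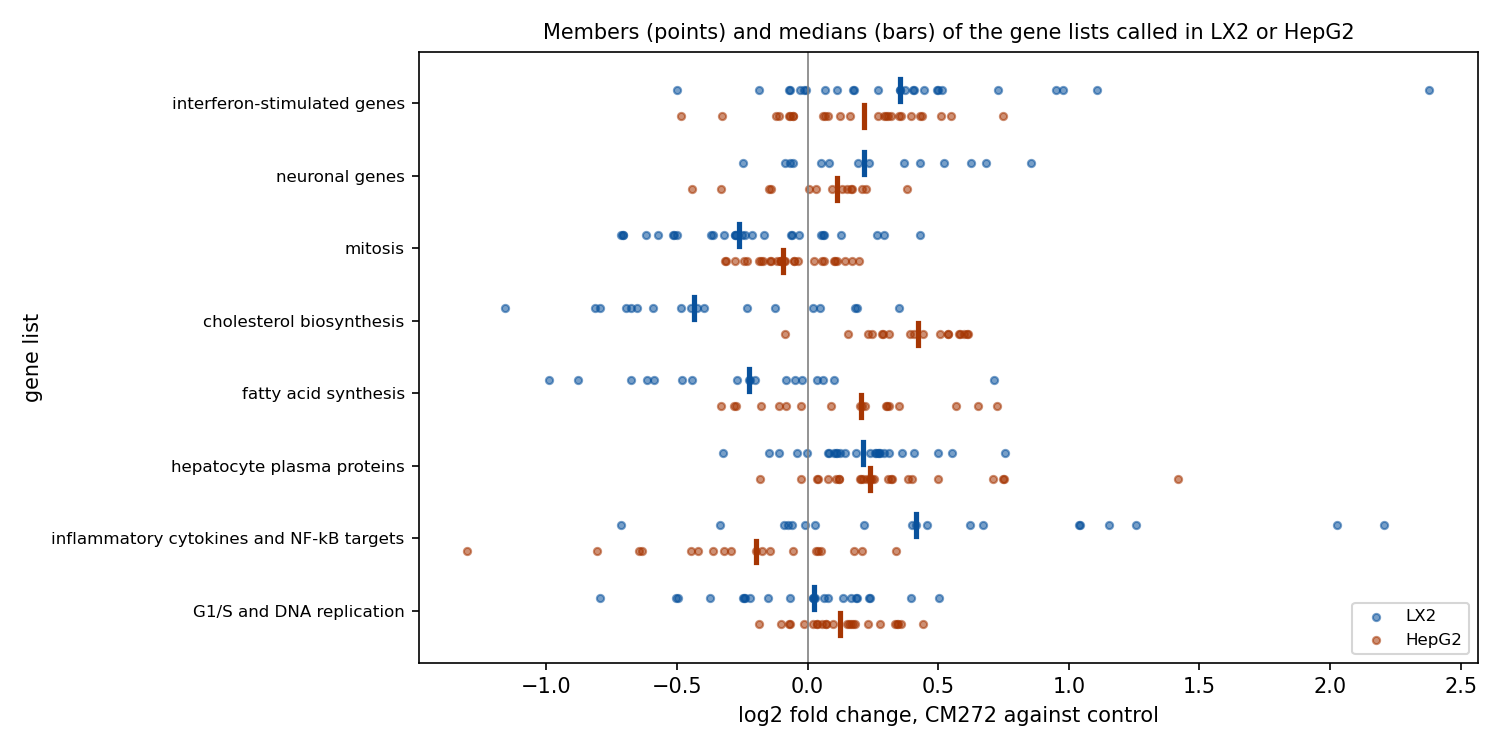
Log2 fold change of CM272 against control (x axis) for the members of the 8 gene lists that passed camera in LX2 or HepG2 (y axis); points are genes and bars are list medians, for LX2 above and HepG2 below. The cholesterol list has medians of -0.43 in LX2 and 0.42 in HepG2, and the inflammatory list of 0.41 and -0.20.

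Whether CM272 acted differently in the lines was tested as the change in HepG2 minus the change in LX2. The change differed for 145 genes in limma, 44 with a positive and 101 with a negative difference, at adjusted p-values down to 2.45e-05. Of these, 0 of the positive and 17 of the negative were called in each of the 8 limma fits that left out 1 array (2153 genes had an unadjusted p under 0.05 with all arrays). The genes that rose most in LX2 led the negative side, with TEX14 (-5.61, SE 0.33), USP17L12 and USP17L9P (-4.64, SE 0.24), FOSB (-4.18, SE 0.21) and ZNF280A (-4.15, SE 0.23). SQLE led the positive side (1.76, SE 0.22, adjusted p = 0.0085), followed by the homeobox gene HOXB4 (1.76, SE 0.26), the lysophospholipid acyltransferase MBOAT1 (1.61, SE 0.26), the cysteine desulfurase NFS1 (1.60, SE 0.22) and KDELR3, a retrieval receptor of the endoplasmic reticulum (1.60, SE 0.27).

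The difference had a median of 0.85 over the 18 cholesterol genes. SQLE, HMGCS1 (1.28, SE 0.22), MSMO1 (1.17, SE 0.20) and INSIG1 (0.97, SE 0.19, with HepG2 means of 3.07 and 3.23 under the brightness filter) passed, 13 did adjusted over the list alone, and the camera adjusted p = 3.42e-08 was lost with an adjusted p = 0.884 with an estimated correlation. The median difference of the fatty acid synthesis genes was 0.34. Of 18 members 2 passed the test, ACSS2 at 1.25 (SE 0.23) and SCD at 1.19 (SE 0.21), and 3 did adjusted over the list alone. That list's camera adjusted p = 0.0038 was lost with an adjusted p = 0.884 with an estimated correlation, and with 0.0878 without LX2 CM272 replicate 2. The median difference of the inflammatory genes was -0.72. Of 19 members 4 passed the test, CCL20 (-2.35, SE 0.36), PTGS2 (-2.17, SE 0.31), ICAM1 (-1.40, SE 0.23) and the growth factor gene CSF3 (-1.33, SE 0.22). Adjusted over the list alone 12 were lower and 1 higher, and the camera adjusted p = 2.54e-07 was lost with an adjusted p = 0.402 with an estimated correlation. Without either LX2 control array none of the members of these 3 lists was called in limma (0 in each, against 13 higher cholesterol, 6 higher fatty acid and 12 lower and 1 higher inflammatory genes at an unadjusted p under 0.05 with all arrays). OASL (-2.50, SE 0.27) and IFI44L (-1.59, SE 0.20) differed as well, although the interferon list did not (median -0.05, camera adjusted p = 0.392). The remaining single genes past the test included ATF3 (-2.35, SE 0.30), IL11, a cytokine induced by TGF-beta (-1.58, SE 0.28), SNAI1 (-4.04, SE 0.22), ERRFI1 (-1.22, SE 0.23), PEG10 (-1.09, SE 0.21), LOX (1.17, SE 0.21) and MEST (1.28, SE 0.19). Both HepG2 means lay under the filter of log2 4 for TEX14, USP17L12, USP17L9P, USP17L15 (-3.72, SE 0.30), PCDH10 (-2.61, SE 0.26), LXN (1.45, SE 0.21), MBOAT1, PTGS2 and IFI44L, and 1 mean did for HOXB4 and CCL20, so that the sizes of their differences are not exact.

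**Figure D3:**
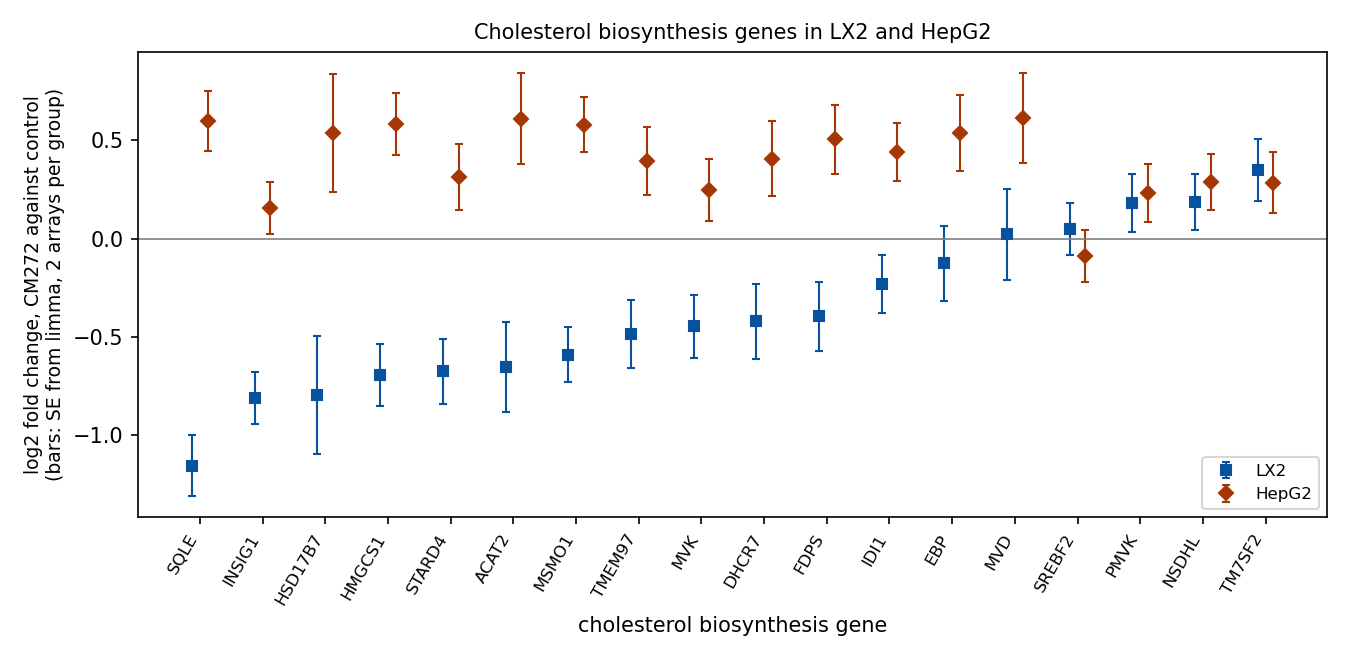
Log2 fold change of CM272 against control (y axis, error bars are limma's SE, 2 arrays per group) for the 18 tested genes of cholesterol biosynthesis, ordered by their change in LX2; squares are LX2 and diamonds HepG2. SQLE, at -1.16 in LX2, has the largest fall, and 17 of the 18 HepG2 values lie above 0.

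With 1 call in HepG2, the overlap of calls between the lines (0 in limma, against 0.0463 expected for the lower genes) could not be assessed, and 3098 and 1403 genes had an unadjusted p under 0.05. The fold changes in the lines correlated weakly across the 12239 genes (Pearson's r = 0.09, Spearman's rho = 0.11, genes not being independent replicates), and 596 of the 1031 LX2 calls (57.8%) had the same sign in HepG2. These were 242 of the 464 higher calls (median in HepG2 0.01) and 354 of the 567 lower calls (median -0.06). In the brightest of 4 groups of genes of like size the median change was -0.14 in LX2 and -0.09 in HepG2, which can favour a shared sign among lower calls. The count of 145 differing genes ran from 19 (0 positive in limma) without LX2 control replicate 1 to 961 (583 positive and 378 negative) without LX2 CM272 replicate 2. It was 20, 263, 28, 36, 68 and 29 without LX2 control replicate 2, LX2 CM272 replicate 1, HepG2 control replicates 1 and 2 and HepG2 CM272 replicates 1 and 2, and fry called none of the lists (0 calls, smallest adjusted p = 0.0918).

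The control cells of the lines were compared to show what each line expresses. HepG2 expressed liver secretory genes far above LX2, with APOH, beta-2 glycoprotein I (10.42, SE 0.15), ALB, albumin (9.65, SE 0.13), AFP, alpha-fetoprotein (9.44, SE 0.14), and APOB, the protein of low-density lipoprotein (9.41, SE 0.14), and also LYZ, lysozyme (9.44, SE 0.13). LX2 expressed more ANXA1, annexin A1 (-8.04, SE 0.16), MSN, moesin (-7.50, SE 0.14), SRGN, a proteoglycan core protein (-7.20, SE 0.20), INSIG1 (-7.17, SE 0.13) and IL7R (-6.99, SE 0.25). The lower of the lines lay under log2 4 for each of these 10 genes except MSN, so that the sizes are not exact. Of 26 hepatocyte plasma proteins 25 were higher in HepG2 (25 adjusted over the list alone, median 5.02). Of 17 stellate cell markers 14 were higher in LX2 and 1 in HepG2 (14 and 1 adjusted over the list alone), with VIM, vimentin, at -6.52 (SE 0.13) and GREM1, a BMP antagonist, at -5.98 (SE 0.15). In HepG2 16 of 18 cholesterol genes and 27 of 28 mitosis genes were lower, as they were adjusted over the list alone.

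In total 7113 genes differed between the control groups (2161 higher and 4952 lower in HepG2, limma with Benjamini-Hochberg adjustment). The median over all tested genes was -0.27, which median centring moved to -0.05 with 3034 genes higher and 3733 lower, so that small differences near -0.27 are not interpretable one by one. Camera called 15 of 32 lists, higher in HepG2 for plasma proteins, hepatocyte transcription factors, fetal liver genes, gluconeogenesis, p53 targets, unfolded protein response and one-carbon metabolism, and lower for stellate markers, matrix, contractile genes, mitosis, G1/S, cholesterol, interferon-stimulated genes and silenced tumour suppressors. No list passed with an estimated correlation (0 calls, smallest adjusted p = 0.108 with an estimated correlation), whereas fry called 28.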

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

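The test for a single aberrant array was chosen only after the result was seen, as were the median of the LXR targets without APOC1 and the conditions that the tested DUX4 targets also stay low and that genes under the brightness filter exclude nothing; the other tests were written down before their results.

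The change with CM272 differed between HepG2 and LX2 by limma's test of the difference (HepG2 minus LX2, adjusted p under 0.05) for 145 genes and for 3 lists by camera, with medians of 0.85 for cholesterol biosynthesis, 0.34 for fatty acid synthesis and -0.72 for inflammatory cytokines and NF-kB targets. None of the list differences passed with an estimated correlation (adjusted p = 0.884, 0.884 and 0.402 with an estimated correlation), which decides little, as it passed no list between the control groups either. None passed with fry (0 calls, smallest adjusted p = 0.0918). Among the named genes the difference was negative for TEX14 (-5.61), USP17L12 and USP17L9P (-4.64 each, the same array values), FOSB (-4.18), ZNF280A (-4.15), SNAI1 (-4.04), USP17L15 (-3.72), RELN (-3.65), GTF2B (-2.79), PCDH10 (-2.61), OASL (-2.50) and C5AR1 (-2.48). It was also negative for CCL20 (-2.35), ATF3 (-2.35), PTGS2 (-2.17), IFI44L (-1.59), IL11 (-1.58), ICAM1 (-1.40), CSF3 (-1.33), ERRFI1 (-1.22) and PEG10 (-1.09). It was positive for INSIG1 (0.97), LOX (1.17), MSMO1 (1.17), SCD (1.19), ACSS2 (1.25), HMGCS1 (1.28), MEST (1.28), LXN (1.45), IPP (1.49), KDELR3 (1.60), NFS1 (1.60), MBOAT1 (1.61), HOXB4 (1.76) and SQLE (1.76). The sizes are not exact for TEX14, USP17L12, USP17L9P, USP17L15, PCDH10, PTGS2, IFI44L, INSIG1, LXN and MBOAT1, whose HepG2 means both lay under the brightness filter of log2 4, nor for CCL20 and HOXB4, with 1 mean under it. RELN was already bright in control HepG2 (11.07, against 4.68 in control LX2). Outside the named genes, 874 of 17658 probe sets with no gene symbol passed limma in LX2 when all probe sets were tested (502 higher and 372 lower), and none did in HepG2 (0, with 1614 at an unadjusted p under 0.05).

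Far more genes were called in LX2 (1031) than in HepG2 (1). A larger spread between the HepG2 arrays could not set these 2 counts apart, as both used 1 variance pooled over the groups (median SE 0.167 in each). With each line fitted alone 198 genes were called in LX2 and 0 in HepG2 in limma. For those counts a larger HepG2 spread is argued against, since the median within-group SD in HepG2 was 0.74 of that in LX2. Changes were smaller in HepG2, where the SD of fold changes left after subtracting the replicate spread was 0.56 of that in LX2 (0.182 against 0.325). With the same SE in both lines fewer calls mean smaller measured fold changes, noise included, so smaller changes describe the counts and are not a separate test. The pooled SE was too small for the wider LX2 spread and too large for HepG2, which by itself favours calls in LX2. With array weights, which leave the fold changes as they are, 283 genes were called in LX2 and 5 in HepG2. Part of the gap between 1031 and 1 therefore rests on pooling the variance. Line and serum level (10% against 2%) went together, so a weaker response of the line and an effect of serum both stay open and were not tested apart. The numbers themselves move with single arrays, from 56 to 2493 calls in LX2 and from 0 to 1 in HepG2.

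The median change of the cholesterol biosynthesis genes was -0.43 in LX2, where 5 of 18 passed limma, and 0.42 in HepG2, where none did (0, with 9 at an unadjusted p under 0.05), and both list calls were lost with an estimated correlation (adjusted p = 0.635 and 0.685 with an estimated correlation). Compression of bright genes on the LX2 CM272 arrays is argued against as the whole cause, since brightness-matched random lists had a median of -0.12. Of 10000 such lists 0.0700% had a median as low. That percentage is likely too small, as their genes were drawn independently, against an estimated correlation of 0.31 within the list. The list was also picked for its change in these data. A candidate explanation is that sterols accumulated in LX2 and lowered the pathway by feedback, for which LXR targets were tested: their median in LX2 was 0.45 (0.40 over the 5 without APOC1, too dim in LX2 to count), and MYLIP, which degrades the LDL receptor, passed limma (0.96, adjusted p = 0.0081). This remains a hypothesis, as PLTP (0.51), APOE (0.40), LPCAT3 (0.21) and RAB11FIP1 (0.06) did not pass and sterols were not measured. The set held only these 6 genes, so its median speaks for them alone and not for LXR targets as a class. No random lists matched on brightness were drawn for it. Serum, a source of cholesterol that differed between the lines, stays open because it is confounded with the line.

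USP17L genes and ZNF280A, which are also targets of the embryonic transcription factor DUX4, rose in LX2. Activation of the whole DUX4 program is argued against, since 28 other targets had a median of 0.27 (quartiles -0.01 and 0.38, and a median of 0.11 in the 15 bright enough to test), although USP17L10 (1.95, adjusted p = 0.0039 in limma) and TRIM43B (1.03, adjusted p = 0.0059) rose. A single aberrant array is argued against as well, because the smallest rise over the highest LX2 control array was 1.74 on either LX2 CM272 array, over ZNF280A and all USP17L genes bright enough to test. ZNF280A, USP17L12, USP17L9P and USP17L15 were named by a rule that asked for both LX2 CM272 arrays beyond both control arrays. For them a rise on both arrays, though not its size, was built in. The 7 germline genes bright enough to test had a median of 0.10 in LX2 and only TEX14 passed limma, so no broad rise was seen among those. For the rest, broad derepression cannot be told apart from a narrower one, as the 13 germline genes too dim to test had a median of 0.13 near the floor. Release of these loci by loss of the inhibited enzymes may apply but was not tested, and the 5 USP17L probe sets gave only 4 different value profiles, so they are not independent genes, and 4 of the 5 were over log2 1 higher (lowest 0.90, a second probe set of USP17L9P outside the array test above).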

How the results depend on the processing

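The fit without the LX2 CM272 group (1 call in HepG2) and the members called per list without each LX2 CM272 array were chosen after seeing the data; the other alternatives were planned. The LX2 count of 1031 was 283 with array weights, 198 with each line fitted alone, 217 with a 2-fold minimum, 160 at an adjusted p under 0.01, 354 by B over 0, and 56 to 2493 leaving out 1 array. The HepG2 count of 1 was 2 with no filter, 4 with the filter at 6, 0 over all probe sets, 4 with the trend and robust prior, 5 with array weights, 0 with the line alone, 6 with the replicate block, 0 at an adjusted p under 0.01, 28 by B over 0, and 0 to 1 leaving out 1 array (1403 at an unadjusted p under 0.05 in limma with all arrays). The difference count of 145 was 79 with no filter, 371 with the filter at 6, 265 over all probe sets, 286 with the trend and robust prior, 71 with the replicate block, 27 at an adjusted p under 0.01, and 19 to 961 leaving out 1 array. The baseline count of 7113 was 15425 over all probe sets, 3495 with a 2-fold minimum, 3627 by B over 0, and 5648 to 7935 leaving out 1 array. The overlap of 0 was 1 with the filter at 6, the trend and robust prior or the block. Stricter thresholds and the 2-fold minimum call fewer genes, and all probe sets test more features, by construction. Array weights, the prior, the block, the single-line fits and leaving out an array of the other line keep a line's fold changes. There the counts of that line move only through the SE and its degrees of freedom. For the other alternatives the cause was not tested. Where a group was left with 1 array, that array is assumed to vary like the other groups.

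None of the 115 named gene results turned direction in an alternative where it passed the threshold in the main fit or in that alternative. Sign changes of results that passed in neither were not counted. Array weights, the variance prior, the block and the single-line fits leave the fold change itself unchanged, so they could not turn a direction. The threshold was lost by 83 without LX2 control replicate 2, 73 without LX2 control replicate 1, 46 of 87 with each line alone, 43 and 40 without HepG2 control replicates 1 and 2, 42 with array weights, 0 of the 103 past the filter at 6, and 0 with the trend and robust prior in limma. Of 15 list calls, 1 reversed: the plasma protein median in LX2 was -0.0087 without LX2 CM272 replicate 1 (range -0.0087 to 0.33 leaving out 1 array), and the cause was not tested. Median centring kept all 15 list calls, LX2 CM272 replicate 2 was needed for 6, and the estimated correlation and fry kept 0 (camera called 15). Replicate numbers did not pair the arrays, since deviations correlated at 0.08 in LX2 and 0.07 in HepG2. Signal over background limits what dim genes can show, and 2645 genes were too dim to test.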

Other observations

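The count of genes called in every fit, and NPPC, DLL4, CXCR4, DKK2, SEPTIN4, HEXIM1, CRABP2, GSTM3, GRAMD1C and EGR1, were chosen after the values were seen; the fits without 1 array were planned, and the test of the immediate-early class was written down before its result.

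Of the 1031 genes called in LX2, 48 were called in every fit that left out 1 of the 8 arrays (44 higher and 4 lower), among them all of the 10 largest rises and MEST. In this set NPPC, which encodes C-type natriuretic peptide, rose by 2.46 (SE 0.19, limma adjusted p = 2.49e-04), and the Notch ligand DLL4 by 2.33 (SE 0.26). The chemokine receptor CXCR4 rose by 1.73 (SE 0.17) and the Wnt modulator DKK2 by 1.67 (SE 0.16). In HepG2 NPPC lay at 0.01, CXCR4 at -0.25 and DKK2 at 0.09, and the difference passed limma for each of these 3 (adjusted p = 0.0041, 0.0072 and 0.0147) but not for DLL4 (0.0598).

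Other genes with known functions were in the same set. SEPTIN4, a septin expressed in stellate cells, rose by 2.13 (SE 0.15, limma adjusted p = 1.49e-04) and HEXIM1, an inhibitor of the elongation factor P-TEFb, by 1.62 (SE 0.14). CRABP2, a carrier of retinoic acid, rose by 1.82 (SE 0.20) and GSTM3, a glutathione transferase, by 1.77 (SE 0.15). GRAMD1C, a sterol transfer protein, fell by 1.19 (SE 0.14).

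FOSB (4.16), EGR1 (1.75, adjusted p = 0.0048) and ATF3 (1.76) rose together in LX2, and induction of immediate-early genes as a class may account for it. The median of 13 other immediate-early genes was 0.22, with quartiles of -0.32 and 0.36, which does not decide. FOS (1.14), EGR3 (1.06) and ARC (1.02) passed limma, whereas MYC lay at -0.38 and KLF2 at -0.41. In HepG2 EGR1 lay at -0.84, and its difference between the lines was -2.59 (adjusted p = 0.0087).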
